A study of Arabidopsis thaliana with 6 samples.

How the data were processed

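Total RNA of Arabidopsis thaliana plants was hybridised to 1-colour Affymetrix Arabidopsis Genome GeneChip arrays after biotin labelling, per the labels' protocols. The series holds 6 arrays in 2 groups of 3: wild type, and 35S:PCO1, plants in which the cauliflower mosaic virus 35S promoter drives PCO1 (plant cysteine oxidase 1). Every plant had been kept in the dark at 5% oxygen for 4 h. The labels give the tissue as rosettes in one field and whole plants in another, and the age as 4 weeks in one field and 5 weeks in another, so both are left open here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be partly technical.

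The deposited values are on the log2 scale and were made by the authors with RMA (robust multi-array average), per the submitters' processing notes; no version, software or probe definition is given in the sources used here. RMA corrects background, quantile-normalizes probe intensities across arrays and summarises each probe set by median polish, so a shift common to all probe sets of an array is removed, and values near the lower end are compressed. No detection calls were used here, and dim probe sets are therefore described by their values only. The table holds 22810 probe sets per array, of which 64 are controls, leaving 22746 that were tested. Array medians lay between 5.87 and 5.91, and the lowest values between 2.73 and 2.81. The number of arrays limits the precision.

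Gene names came from the platform annotation, an older table, updated by gene number through the TAIR10.1 gene table, which was used only for names and for gene order. Of the probe sets tested, 13513 have 1 gene, 503 have several and 8730 are not listed in the annotation used here, and the 1-gene probe sets cover 13333 loci. Unlisted probe sets were tested but have no name here. Probe sets with several genes were not used to name genes. No coordinates are printed, because no genome build is named for the probe sets. The annotation used here pairs no probe set with PCO1 or the rest of its family, so the planned measurement of the transgene is not reported here.

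The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, 2-sided, and with Benjamini-Hochberg adjustment over all tested probe sets. A probe set was called at an adjusted p under 0.05. Values are given as the log2 change of 35S:PCO1 minus wild type with its standard error (SE), with 3 arrays per group throughout. Before the data were examined, 22 gene lists were fixed by locus: hypoxia-responsive genes, the PCO family, fermentation, sucrose and glycolysis, group VII ethylene response factors and the N-degron pathway, ethylene, heat shock, antioxidants, cysteine and sulfur, photosynthesis, the circadian clock, dark and sugar starvation, salicylate defence, jasmonate and wounding, abscisic acid with cold and drought, iron, flavonoids, nitrate and nitric oxide, markers of roots, flowers and seeds, and reference genes. Each gene was represented by its probe set with the highest mean. The 9 lists with at least 3 matched genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 9 lists; the other 13 matched fewer, 5 of them none. The list mean per array was also compared by an exact 2-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

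The genes named were chosen by a rule fixed at the same time. It took PCO1 and its family; up to 12 genes with the highest and 12 with the lowest log2 change among called probe sets that name 1 gene and whose groups do not overlap; and up to 4 called members of each list, or the 2 members with the largest change where none was called. In addition, the 2 unlisted probe sets with the highest and the 2 with the lowest change are given by their values.

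RNA quality was compared by the log2 signal of the 3 prime minus the 5 prime control probe sets of GAPDH, actin and ubiquitin. Alternatives were the replicate number as a block, centring of each array on its median, a repeated quantile normalization, eBayes with trend and robust settings, array weights, only probe sets above the 40th percentile of mean signal, exclusion of probe sets with less specific names, other thresholds, each array left out in turn, camera with an estimated correlation, fry, and the mean of all probe sets of a gene. Lists of plastid-encoded and mitochondrially encoded genes, an enrichment by Fisher's exact test and a test of neighbouring genes were added after the data were seen. The procedure was tested on simulated data with the real means and the eBayes-moderated spreads of this comparison, where 22746 probe sets were fitted. Noise was drawn independently, without correlation between genes or a deviating array. The procedure called 94% of the 50 probe sets given a log2 change of 0.5 and 100% of those given 1. It also called 18 probe sets given no change, beside 47, 50 and 100 true calls at changes of 0.5, 1 and 2. These shares may overstate the power in the real data, where AT4G39675 with a log2 change of -1.53 was not called (adjusted p = 0.071). Figures were drawn with matplotlib 3.10.9.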

Results

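Gene expression was measured in Arabidopsis plants kept for 4 h in the dark at 5% oxygen, on 3 arrays of wild type and 3 arrays of 35S:PCO1, a line that overexpresses a plant cysteine oxidase. Plant cysteine oxidases use oxygen to oxidise the N-terminal cysteine of group VII ethylene response factors, which marks these transcription factors for degradation; the same factors activate genes of the hypoxia response. The design therefore asks how raised PCO1 alters the transcriptome of plants that are short of oxygen. No plants in normal air are analysed here, so the values compare the genotypes under hypoxia and do not measure induction. The level of PCO1 itself is not analysed here, because the annotation used here pairs no probe set with it, and the transgene thus gave no check of the labels. The 6 arrays covered 22746 tested probe sets, with correlations between arrays from 0.994 to 0.999 across probe sets.

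Genes of the hypoxia response were lower in 35S:PCO1 than in wild type. Of the 46 genes on the list fixed in advance, 24 could be matched to a probe set, and 10 of these fell, none rose and 14 were not called. AT4G10270, a member of the wound-responsive protein family, fell by 2.54 on the log2 scale (SE 0.19, 5.81-fold lower, adjusted p = 0.00064), from 8.83 ± 0.33 (SD, n = 3) in wild type. AT1G33055 was 4.09-fold lower (log2 change -2.03, SE 0.15, adjusted p = 0.00067). CML38, which encodes a calmodulin-like protein, was 2.45-fold lower (log2 change -1.29, SE 0.094, adjusted p = 0.00064), and its 3 wild-type values had an SD of 0.021. Its 35S:PCO1 mean of 4.40 lies near the lower end of the scale, where RMA compresses changes, so that fold may understate the difference. AT3G10040, which encodes the trihelix transcription factor HRA1, an attenuator of the hypoxia response, was 2.61-fold lower (log2 change -1.38, SE 0.14, adjusted p = 0.0044).

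The other named members of this list that fell were AT1G19530 with a log2 change of -2.08 (SE 0.28), AT2G17850 of the rhodanese family with -1.81 (SE 0.21), AT3G27220 of the Kelch-repeat family with -1.40 (SE 0.078), and AT5G10040 with -0.90 (SE 0.084). With 1 array left out, the log2 changes of AT1G19530 and AT2G17850 ranged from -2.44 to -1.83 and from -2.10 to -1.60. Their adjusted p of 0.022 and 0.012 rose to as much as 0.21 and 0.12, and both calls ended when any 1 of 4 arrays was left out (wild type replicate 1 and each 35S:PCO1 array), with fewer samples; the call of AT1G19530 also ended with the trend and robust options of eBayes (adjusted p = 0.14). Members that were not called included PDC2, a pyruvate decarboxylase of ethanol fermentation, with a log2 change of -0.31 (SE 0.071, adjusted p = 0.19). With array weights, PDC2 had a log2 change of -0.35 and was called (adjusted p = 0.037). Among the 24 members the change ranged from -2.54 to 0.12, and 22 of the changes were negative.

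**Figure D1:**
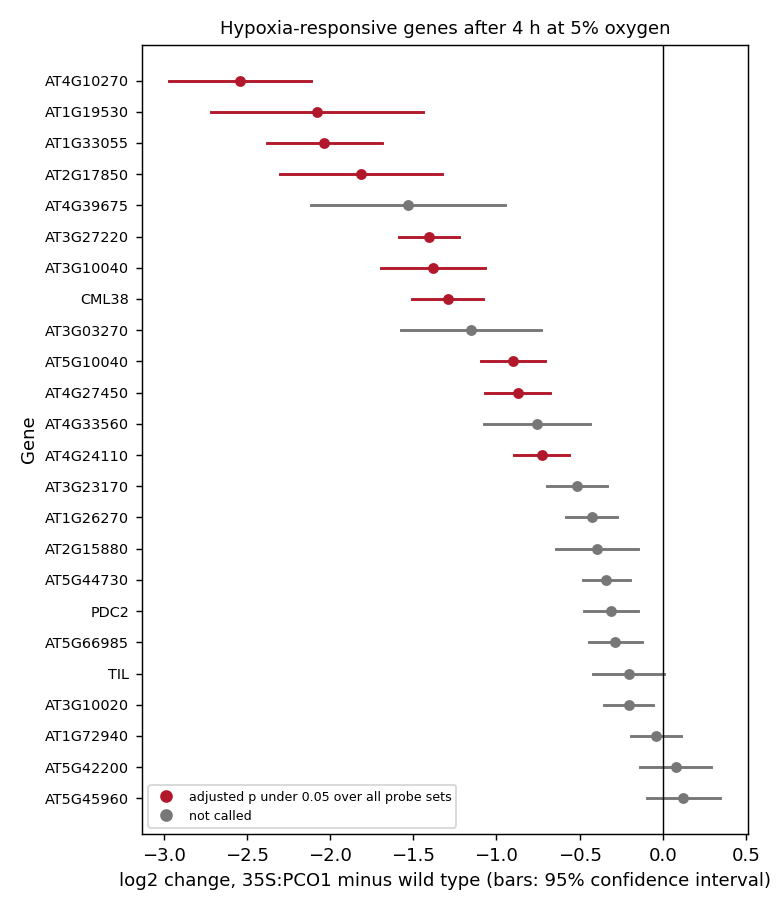
Log2 change of 35S:PCO1 minus wild type (x axis) for each of the 24 matched genes of the hypoxia list (y axis), with 95% confidence intervals as bars and 3 arrays per group; red marks the 10 genes called over all probe sets and grey the 14 that were not called. The points run from -2.54 for AT4G10270 to 0.12 for AT5G45960, and 22 lie below 0.

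As a group, the hypoxia genes had a median log2 change of -0.74, or 1.67-fold, and a mean of -0.88. The list differed from all other probe sets by camera (adjusted p = 8.2e-32 over the 9 lists tested; adjusted p = 0.044 with an estimated correlation). With adjustment over the list alone, 20 members fell and none rose. In 20 members every 35S:PCO1 array lay below every wild-type array, where chance gives 5% for one direction. The mean of the 24 genes per array was 7.29 ± 0.14 (SD, n = 3) in wild type and 6.42 ± 0.072 (SD, n = 3) in 35S:PCO1 (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). In an enrichment test added after the data were seen, 10 of the 24 matched list genes were called lower, against 10 of the other named genes or 0.0751% (2-sided Fisher's exact test over 13333 genes, p = 7.4e-24). That test treats genes as independent, which the list members are not (estimated correlation between genes 0.196), so its p overstates the evidence. The labels do not say whether both genotypes were treated in the same run, so a difference between treatment runs cannot be separated from genotype.

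Across all probe sets, 60 were called, of which 16 were higher and 44 lower in 35S:PCO1. With a log2 change of at least 1 in size, 4 were higher and 18 lower. In all 60 the groups did not overlap, which passing the threshold with 3 arrays per group largely sets beforehand. Among all tested probe sets the share was 16.2%, where chance gives 10%. Of the called probe sets, 27 name 1 gene, 7 higher and 20 lower, and 33 are not listed in the annotation used here. The count of 60 became 23 without wild type replicate 1, 24 without 35S:PCO1 replicate 1 and 33 without 35S:PCO1 replicate 3; it was 255 with array weights, of which 78 were higher and 177 lower. The median change of all probe sets was -0.01.

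Genes higher in 35S:PCO1 included the co-chaperones Fes1A and Hop3. Fes1A (AT3G09350), a nucleotide exchange factor of HSP70, had a log2 change of 1.14 (SE 0.13, adjusted p = 0.0095). Hop3 (AT4G12400), which links HSP70 and HSP90, had a log2 change of 0.86 (SE 0.12, adjusted p = 0.033) and was dim, at 3.28 ± 0.055 (SD, n = 3) in wild type, close to the lower end of the values. The largest named increase was AT1G43590, with a log2 change of 1.86 (SE 0.27, adjusted p = 0.035) and a wild-type SD of 0.66. AT3G55760 rose by 0.86 (SE 0.063, adjusted p = 0.00064), and AT1G07050, a CCT motif family gene, by 0.68 (SE 0.057, adjusted p = 0.0014). Smaller increases were those of AT4G10280 with 0.54 (SE 0.079, adjusted p = 0.038) and AT2G14860 with 0.49 (SE 0.074, adjusted p = 0.044). The calls of AT3G55760 and AT1G07050 held without each array in turn, with adjusted p up to 0.010 and 0.018. Those of the other 5 did not. Fes1A missed the threshold without wild type replicate 1 (adjusted p = 0.060) and without 35S:PCO1 replicate 1 (adjusted p = 0.062). Hop3 passed only without 35S:PCO1 replicate 2 or 3, AT1G43590 only without wild type replicate 2 or 3, and AT4G10280 only without wild type replicate 2. AT2G14860 passed in none of these 6 fits. The adjusted p reached 0.25 for Hop3, 0.25 for AT1G43590, 0.25 for AT4G10280 and 0.33 for AT2G14860. With the trend and robust options of eBayes, the calls of AT1G43590 (adjusted p = 0.15) and AT2G14860 (adjusted p = 0.0505) also ended.

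Outside the hypoxia list, the largest named decreases included 3 genes of the lipid-transfer protein superfamily, a family for which no enrichment was tested. AT1G62500 fell by 1.36 (SE 0.067, adjusted p = 9.7e-05), AT4G22490 fell by 1.59 (SE 0.19, adjusted p = 0.011) and AT5G01870 fell by 1.17 (SE 0.12, adjusted p = 0.0054). AT1G19540 fell by 0.99 (SE 0.14, adjusted p = 0.025). The call of AT1G62500 held without each array in turn, with adjusted p up to 0.0019. The call of AT5G01870 ended, at an adjusted p of 0.052, without wild type replicate 1 or 35S:PCO1 replicate 1. That of AT4G22490 ended without wild type replicate 1, 35S:PCO1 replicate 1 or 35S:PCO1 replicate 3 (adjusted p up to 0.12), and that of AT1G19540 without wild type replicate 1 or any 35S:PCO1 array (adjusted p up to 0.21). Of the 19 called genes named in all, 9 kept their call without each array in turn.

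**Figure D2:**
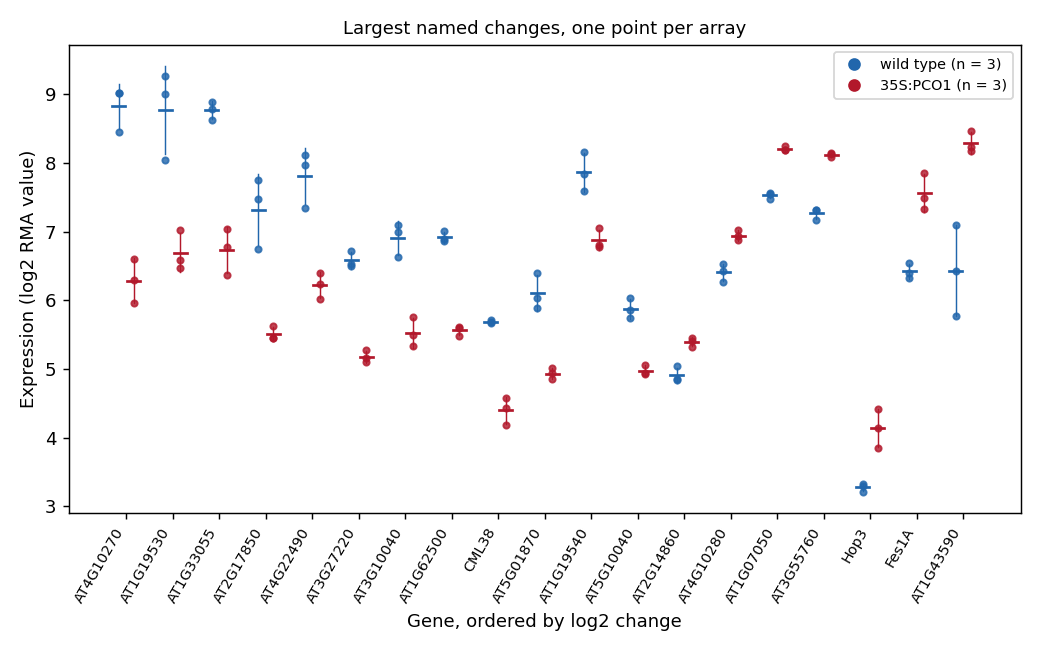
Log2 RMA expression (y axis) of the 19 called genes with the largest named changes (x axis, ordered by change) on each array, with blue points for wild type and red points for 35S:PCO1; horizontal bars are means and vertical bars SDs of 3 arrays. The log2 change runs from -2.54 for AT4G10270 at the left to 1.86 for AT1G43590 at the right. The groups overlap for none of the 19 genes, as the rule that chose them required.

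Among the probe sets that the annotation used here does not list, the most increased rose from 8.66 ± 0.037 (SD, n = 3) in wild type to 11.4 ± 0.24 (SD, n = 3) in 35S:PCO1, a log2 change of 2.72 (SE 0.11, adjusted p = 4.3e-05). The next had a log2 change of 1.04 (SE 0.13, adjusted p = 0.016), and its adjusted p reached 0.12 when 1 array was left out. The most decreased was 8.78-fold lower (log2 change -3.13, SE 0.16, adjusted p = 9.7e-05), a fold that may understate the difference because its 35S:PCO1 mean of 4.06 lies near the lower end of the scale. The next was 4.77-fold lower (log2 change -2.25, SE 0.15, adjusted p = 0.00034). The genes that these 4 probe sets measure are not named here.

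None of the other 8 tested lists differed between the genotypes by camera, although 2 of these lists had an unadjusted p under 0.05. These results cover the matched genes only, which were a minority of each list. Matched were 4 of 19 genes of abscisic acid, cold and drought, 3 of 9 reference genes and 3 of 12 root markers. For sucrose and glycolysis it was 8 of 30, for photosynthesis 4 of 25 and for heat shock 3 of 16. For antioxidants it was 4 of 20 and for flavonoids 3 of 12. None of their members was called by limma, which gave 2362 of all probe sets an unadjusted p under 0.05. The 4 matched genes of abscisic acid, cold and drought had a median log2 change of 0.12 (adjusted p = 0.087 by camera), with COR15A, a chloroplast protein of freezing tolerance, at 0.17 (SE 0.063) and LTI30, a dehydrin, at 0.14 (SE 0.16). Without wild type replicate 2 this list reached an adjusted p of 0.026, and without 35S:PCO1 replicate 1 an adjusted p of 0.018. Without wild type replicate 3 its median was 0.044 (adjusted p = 0.31). These values rest on the preset correlation of camera. With an estimated correlation, 0.399 for this list, camera on all arrays gave an adjusted p of 0.45. The 3 matched reference genes had a median of -0.14 (adjusted p = 0.12), with AT4G34270 at -0.20 (SE 0.058) and PEX4 at -0.14 (SE 0.073); 1 of them was called lower when adjusted over the list alone, and fry gave the list an adjusted p of 0.043. The 3 matched root markers, which would follow a difference in root tissue between samples, had a median of -0.10 (adjusted p = 0.29), with PYK10 at -0.18 (SE 0.097) and EXPA7 at -0.10 (SE 0.088). All 3 changes were negative, and fry gave an unadjusted p of 0.045. Their mean per array was 5.98 ± 0.072 (SD, n = 3) in wild type and 5.86 ± 0.0089 (SD, n = 3) in 35S:PCO1 (exact permutation p = 0.1, the smallest possible). A small difference in root tissue therefore stays open.

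The remaining tested lists moved less. Sucrose and glycolysis genes (8 matched) had a median log2 change of -0.030 (adjusted p = 0.82), which was 0.0078 after repeated quantile normalization, with the pyruvate kinase family genes AT5G63680 at -0.10 (SE 0.11) and AT4G26390 at -0.086 (SE 0.090). The 4 photosynthesis genes had a median of -0.019 (adjusted p = 0.82), with PSAN, a subunit of photosystem I, at -0.10 (SE 0.065) and LHCB4.1, an antenna protein of photosystem II, at -0.056 (SE 0.058). The 3 heat shock genes had a median of 0.025 (adjusted p = 0.82), with ATHSP22.0 at 0.096 (SE 0.093) and AT1G53540 at -0.085 (SE 0.069). All 3 were dim, with wild-type means from 3.51 to 4.47, near the lower end of the values, where RMA compresses changes. The 4 antioxidant genes had a median of -0.0079 and a mean of 0.0017, of opposite sign (adjusted p = 0.82), and the median was 0.011 after repeated quantile normalization, with the zinc finger factor STZ at 0.084 (SE 0.11) and glutathione reductase GR1 at -0.062 (SE 0.056). The 3 flavonoid genes had a median of 0.0049 and a mean of -0.025, again of opposite sign (adjusted p = 0.82), with DFR, dihydroflavonol reductase, at -0.20 (SE 0.13) and UF3GT at 0.12 (SE 0.078).

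Lists with fewer than 3 matched genes were not tested, and none of their matched members was called. Few members were matched: 2 of 12 for fermentation, 1 of 14 for the N-degron list and 2 of 19 for ethylene. For cysteine and sulfur it was 2 of 21, for the clock 1 of 14 and for dark and sugar starvation 2 of 15. For jasmonate and wounding it was 2 of 18 and for iron 1 of 12. Unmatched members may be among the 33 called probe sets without a name, so unchanged pathways cannot be inferred. Besides PDC2, the fermentation list had AT4G17260, a lactate dehydrogenase, at a log2 change of -0.33 (SE 0.080, adjusted p = 0.22). The N-degron list had the methionine aminopeptidase MAP1A at -0.037 (SE 0.064), or 0.0035 after repeated quantile normalization. The ethylene list had RTE1 at -0.077 (SE 0.063) and the transcription factor EIN3 at 0.024 (SE 0.073). Cysteine and sulfur metabolism had the sulfite reductase SIR at -0.13 (SE 0.072) and BGLU28 at -0.011 (SE 0.086). The clock list had GI at 0.015 (SE 0.15), and dark and sugar starvation had MCCA at 0.20 (SE 0.15) and AKINBETA1 at 0.016 (SE 0.086). Jasmonate and wounding had the defensin PDF1.2 at -0.46 (SE 0.39) and the thionin THI2.1 at -0.12 (SE 0.11), and the iron list had the transcription factor PYE at -0.15 (SE 0.076). The PCO family, salicylate defence, nitrate and nitric oxide, and the markers of flowers and seeds had no matched gene and were not analysed here.

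The control probe sets for RNA quality did not separate the genotypes. The log2 difference of 3 prime over 5 prime signal was 0.457 ± 0.31 (SD, n = 3) in wild type and 0.431 ± 0.0066 (SD, n = 3) in 35S:PCO1 for GAPDH (exact permutation p = 1). For actin it was 1.57 ± 0.18 (SD, n = 3) against 1.43 ± 0.052 (SD, n = 3), with an exact permutation p = 0.3. For ubiquitin it was 1.02 ± 0.072 (SD, n = 3) against 0.965 ± 0.029 (SD, n = 3), with an exact permutation p = 0.4. The array of wild type replicate 2 stood apart, with 0.813 for GAPDH and 1.78 for actin, and with a score of -18.8 on the first principal component, which held 34.1% of the variance and on which the other arrays lay between -6.13 and 11.6; all wild-type arrays lay below all 35S:PCO1 arrays on it. Wild type replicate 3 stood apart on the second component, which held 30.6% of the variance, with a score of 17.45 against 4.56 for the next array. Without wild type replicate 2 the median log2 change of the hypoxia genes was -0.67, with 10 members called lower, and 60 probe sets were called in all; without wild type replicate 3 these values were -0.78, 15 and 54.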

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

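The tests of the plastid-encoded genes and of a shift of whole arrays were chosen after the results were seen; leaving out wild type replicate 2 was planned, but the bound for the hypoxia genes was set afterwards. A control probe set for 5S ribosomal RNA enters no comparison of the report. It was higher in 35S:PCO1 than in wild type by 0.868 on the log2 scale. Its groups did not overlap (exact permutation p = 0.1, the smallest possible). The same held for 16.2% of the tested probe sets, where chance gives 10%, so this order does not set the 5S control apart. Its values were 4.98, 3.93 and 5.45 in wild type replicates 1, 2 and 3 and 5.66, 5.65 and 5.65 in 35S:PCO1. It was 1 of 13 plant control probe sets looked at, and the control for 25S ribosomal RNA differed by -0.073 (exact permutation p = 0.5).

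Plastid-encoded genes followed the same order: the median log2 change of 69 genes was 0.36, and no single gene was called over all probe sets. Low values on the array of wild type replicate 2 are argued against as the whole cause, since without that array the mean change was 0.206 (SE between arrays 0.035), down from 0.400 (SE 0.20). What stays open is a difference between arrays shared with the 5S control: a line through the 3 wild-type arrays predicted the plastid level of 35S:PCO1 from its 5S value to within 0.0294. That line is extended past the highest wild-type 5S value and rests on wild type replicate 2: a line through replicates 1 and 3 left 0.137 of the 0.206, so this test cannot tell. The genotype also stays open, because 59.4% of the genes had every 35S:PCO1 array above every wild-type array, but these genes are not independent (estimated correlation between genes 0.307), and an array difference of the same order would do the same. RNA input or labelling and genotype cannot be told apart here, and the pattern may be technical.

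The decrease of the hypoxia-responsive genes was weighed against 3 technical explanations. A shift of whole arrays left by the normalization would lower other genes alike. The 32 genes of the other tested lists had a mean log2 change of -0.022 (SE between arrays 0.034) against -0.876 for the hypoxia genes. The median of all probe sets was -0.012, and that of the 3 reference genes was -0.14. RMA gives the arrays a common distribution, so values near 0 over many genes were largely set beforehand. They therefore do not test this explanation, and show only that no uniform shift as large as the hypoxia change is left in the values. The array of wild type replicate 2 is argued against as the cause, because the mean without it was -0.818 (SE 0.090). Different oxygen levels or separate treatment of the 2 genotypes cannot be told apart from genotype, since the labels name a treatment run for 0 of the arrays. A lower hypoxia response through PCO1 activity stays open beside that explanation.

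Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many calls as the real one, namely the real split itself, with 60; the highest of the others gave 0. With 10 splits the share cannot fall under 0.1.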

How the results depend on the processing

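The plastid and mitochondrial lists were added after the data were seen; the other settings were planned. The median change of the hypoxia list kept its direction and passed under each setting run, from -0.67 without wild type replicate 2 to -0.87 among probe sets above the 40th percentile (19 members), with adjusted p at most 0.044. Its members called lower numbered 7 to 15 with 1 array left out and 17 with array weights, against 10. The total of 60 calls (16 higher, 44 lower) became 255 (78 and 177) with array weights, 28 (6 and 22) at an adjusted p under 0.01, and 22 (4 and 18) with a log2 change of at least 1, a stricter threshold by construction. With 1 array left out it ranged from 23 to 60, with 4 to 14 higher and 19 to 46 lower; it was 23 without wild type replicate 1, 24 without 35S:PCO1 replicate 1 and 33 without 35S:PCO1 replicate 3, with fewer samples. With the trend and robust options of eBayes the total was again 60, of which 54 were among the original calls; those of AT1G43590, AT1G19530 and AT2G14860 ended. None of the 60 changed sign in any fit that tested it.

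The replicate number as a block gave 26 calls, 5 higher and 21 lower, and ended 7 of the 23 calls of named genes and unlisted probe sets. No pairing by number showed in the values. Same-numbered arrays had correlations of deviations of -0.059, -0.22 and -0.26. In 0 of 3 pairs did the arrays correlate best with their own number. The labels do not say whether same-numbered arrays shared a treatment run, so a pairing is not excluded.

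Of the other fixed lists, 0 passed; 0 to 1 did with 1 array left out (abscisic acid, cold and drought, without wild type replicate 2 or 35S:PCO1 replicate 1) and 1 with fry (reference genes). The plastid list lost its call with an estimated correlation (adjusted p = 0.061) and with fry (adjusted p = 0.065). Signs turned only in values that were not called. Repeated quantile normalization gave 0.0078 for sucrose and glycolysis, 0.011 for antioxidants and 0.0035 for MAP1A. Array weights gave 0.0036 for sucrose and glycolysis, -0.011 for GI and -0.015 for AKINBETA1. The filter at the 40th percentile gave 0.050 for mitochondrial genes. With 1 array left out, the ranges were -0.032 to 0.024 for flavonoids, -0.063 to 0.011 for sucrose and glycolysis, -0.034 to 0.057 for antioxidants, -0.033 to 0.061 for heat shock, -0.033 to 0.053 for mitochondrial genes, -0.072 to 0.068 for BGLU28, -0.14 to 0.19 for GI, -0.076 to 0.081 for AKINBETA1, -0.075 to 0.0031 for MAP1A, -0.0083 to 0.15 for ATHSP22.0, -0.036 to 0.29 for LTI30, -0.21 to 0.022 for AT5G63680, -0.037 to 0.065 for EIN3, -0.012 to 0.19 for STZ and -0.0097 to 0.31 for MCCA. PDF1.2 and THI2.1 kept their sign but ranged from -0.85 to -0.020 and from -0.24 to -0.041. The cause was not tested for any of these. Settings for PCO1 itself were not run, as no probe set is paired with it here. Signal over background limits dim probe sets such as those of Hop3 and the heat shock genes.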

Other observations

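The lists and tests in this part were all added after the data were seen. Genes encoded in the plastid genome had higher values in 35S:PCO1: of 69 genes, 1 had a negative change, and 15 were called higher and none lower when adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 9.1e-32 over the 2 added lists) but not with an estimated correlation (adjusted p = 0.061), and its mean per array was 8.95 ± 0.34 (SD, n = 3) in wild type and 9.35 ± 0.030 (SD, n = 3) in 35S:PCO1 (exact permutation p = 0.1). Examples chosen after their values were seen are rpl14, a ribosomal protein gene, with a log2 change of 0.69 (SE 0.16, adjusted p = 0.20), and psaA, a core subunit of photosystem I, with 1.29 (SE 0.71, adjusted p = 0.59). The psaA values in wild type were 10.8, 7.74 and 10.99, the lowest on the array of replicate 2. Genes encoded in the mitochondrial genome, 11 of them, had a median change of -0.0099 (adjusted p = 0.69); their mean in wild type was 4.77, towards the dim end, where a change would be compressed.

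One hypothesis examined was that the called genes lie beside each other more often than chance would place them. In the order of 13264 named genes, the 27 called genes formed 2 neighbouring pairs, against a mean of 0.0497 for random sets of the same size (permutation test, 1-sided, 10000 draws, p = 0.00090). The test was added after these called genes were seen and uses the same genes, so its p cannot argue against chance. With 1 array left out, the number of pairs ranged from 0 to 2, as calls of pair members were lost. Without wild type replicate 3, 27 genes were still called but formed 1 pair (permutation p = 0.049). The log2 changes stayed between -2.44 and -1.83 for AT1G19530, -1.12 and -0.84 for AT1G19540 and 0.47 and 0.60 for AT4G10280. With the trend and robust options of eBayes on all arrays, 25 called genes formed 1 pair (permutation p = 0.042). These counts, and the 0 pairs under the replicate block, therefore speak neither for nor against chance. Array weights, which called 135 genes, gave 3 pairs against a mean of 1.37 for random sets (permutation p = 0.16), so chance placement stays open. AT1G19530 and AT1G19540 were both lower, with log2 changes of -2.08 and -0.99. AT4G10270 was lower with -2.54, whereas its neighbour AT4G10280 was higher with 0.54. The opposite directions of the second pair do not follow from a shared decrease.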
